A study of Mus musculus with 10 samples.

How the data were processed

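Microglia were isolated from mouse brains with magnetic beads, total RNA was amplified with the NuGEN Ovation system and libraries were made with the Ion Xpress Plus Fragment kit, per the labels' protocols. The submitters' processing notes name the genome builds GRCm38 and mm10 and the tool FastQC. The aligner, the counter, the annotation and the normalisation are not given in the sources used here, nor is a strand setting, so reads of overlapping genes on opposite strands could not be told apart. Reads shared between near-identical genes may have been split or dropped.

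The values deposited by the authors were read as RPM, a scaling of read numbers by a library total, because in each library most low values were whole multiples of a single step above a constant of 0.0001 that is in every cell. The step was worth 0.101 to 0.164 RPM, which corresponds to 6098274 to 9907451 reads behind the scaling. The listed genes summed to 187237 to 235463 RPM, 18.7% to 23.5% of that total. Of values up to 500 reads, 94.2% to 94.6% per library were within 0.05 of a whole read. The rest were fractions, so whole reads could not be recovered, and no count model was used. The fixed design had expected a normalised unit other than RPKM, FPKM or TPM, and its minimum of 10 was used as written.

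Genes were matched to GENCODE M21 (GRCm38), 23407 by symbol and 625 by a RefSeq synonym, with 421 unmatched or ambiguous. Genes with at least 10 RPM in at least 2 of 10 libraries were tested. Values were transformed to log2(RPM + 1) and fitted with limma 3.58.1 in R 4.3.3 as 4 groups sharing 1 estimate of the spread, with 6 residual degrees of freedom and a mean-dependent prior variance. The contrasts were aged minus young, labelled deltaMG minus labelled control, and the difference between them. Benjamini-Hochberg adjusted p under 0.05 defined a call. Figures were drawn with matplotlib 3.10.9.

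Gene lists and cell type markers were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over 19 lists with at least 3 tested members. Some lists share members, so their results are not independent. With the estimated correlation none of the lists passed in either comparison. The planned rotation test fry asks whether a list moved at all, and its p is unadjusted. For aged minus young and then labelled deltaMG minus labelled control, fry p was 0.00119 and 0.00076 for disease-associated genes. It was 0.00207 and 0.777 for homeostatic and 0.819 and 0.00335 for lysosomal genes. For neutrophil genes it was 0.157 and 0.0924, for monocyte genes 0.0506 and 0.0838. Other fry values are not reported here. The lists covered the interferon response, MHC class I and II, disease-associated and homeostatic microglia, cytokines, lysosomal genes, vacuolar ATPase, late endosome fusion, autophagy, lipid transport, phagocytosis, iron, cell cycle, oxidative phosphorylation, immediate early genes, ribosomal proteins, cholesterol synthesis, mitochondrially encoded genes and markers of other brain and blood cells.

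Named genes were Rab7, up to 10 largest rises and 10 largest falls among called genes with a mean of at least 50 RPM and no overlap of ranges, up to 4 members per list with the smallest p, and up to 10 genes called in both comparisons. Other members given by name as called in a list, or in both comparisons, were chosen after their values were seen. Some genes that met the rule are not reported here. The design, the lists, the naming rule and the alternative settings were fixed before the data were examined.

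The fit was tested on simulated data in which 100 genes per fold size and comparison were changed, among 17493 simulated genes of which 4061 passed the filter. In the ageing comparison 83% of 2-fold and 94% of 4-fold changes were called, with 7 false among 184 calls. In the comparison of the libraries labelled deltaMG and control these were 63% and 98%, with 7 false among 168 calls. The simulated genes varied independently, each with the same spread in all libraries. Real genes moved together, with an estimated correlation of 0.90 in the neutrophil list, so these rates need not hold for the real libraries. Alternatives covered the filter, pseudocount, scaling, samples in the fit, replicate block, variance moderation, weights, threshold and leaving out each library. Voom on reads estimated from the steps, a minimum of 1 RPM, a neutrophil score as covariate, leaving out Xist and Y-linked genes and exchanged labels for the difference of effects were added after the data were seen.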

Results

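RNA was sequenced from microglia, the resident macrophages of the brain, isolated from C57BL/6 mouse brains with magnetic beads. The 10 libraries fell into 4 groups. In the ageing comparison, 3 libraries came from mice aged 15 months and 3 from mice aged 10 weeks, called aged and young here. In the other comparison, 2 libraries were labelled Rab7 deltaMG and 2 were labelled Rab7 control, from mice aged 3 months. Rab7 encodes a small GTPase of late endosomes and lysosomes, and the series names the first of these groups as null mutants. Values were RPM, read numbers scaled to a common library total, for 24453 gene symbols. The low values gave a depth of 6098274 to 9907451 reads per library behind the scaling, of which 1284409 to 1855045 lay in the listed genes. The ribosomal RNA precursor Rn45s took 7.64% to 11.8% of the listed signal. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these libraries, part of which may be technical.

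The gene named in the labels was examined first. Rab7 (chromosome 6, 87999106 to 88045270, minus strand, GRCm38) was measured at 65.9 RPM ± 2.37 (SD, n = 2) in the libraries labelled control and at 75.8 RPM ± 5.13 (SD, n = 2) in those labelled deltaMG. The log2 fold change was 0.20 with a standard error of 0.20 and a limma adjusted p of 0.668. Its sign is not fixed, since with the neutrophil marker score of each library as a covariate, a fit added after the data were seen, it was -0.21 (adjusted p = 0.644), and the neutrophil list was higher in the libraries labelled deltaMG. In neither fit was Rab7 measurably lower in the libraries labelled deltaMG. The table gives 1 value per gene, so reads from exons that a deletion would leave in place cannot be separated from the rest. The individual values were 64.2 and 67.5 RPM in the libraries labelled control and 72.2 and 79.4 RPM in those labelled deltaMG. Because Rab7 does not check the labels, these groups are called the libraries labelled control and the libraries labelled deltaMG throughout, and each direction below rests on those labels. Rab7 was at 65.0 RPM ± 6.74 (SD, n = 3) in young and 76.9 RPM ± 22.5 (SD, n = 3) in aged libraries, a log2 fold change of 0.21 with a limma adjusted p of 0.536, which was -0.02 without aged replicate 3 and -0.06 with the neutrophil score.

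**Figure D1:**
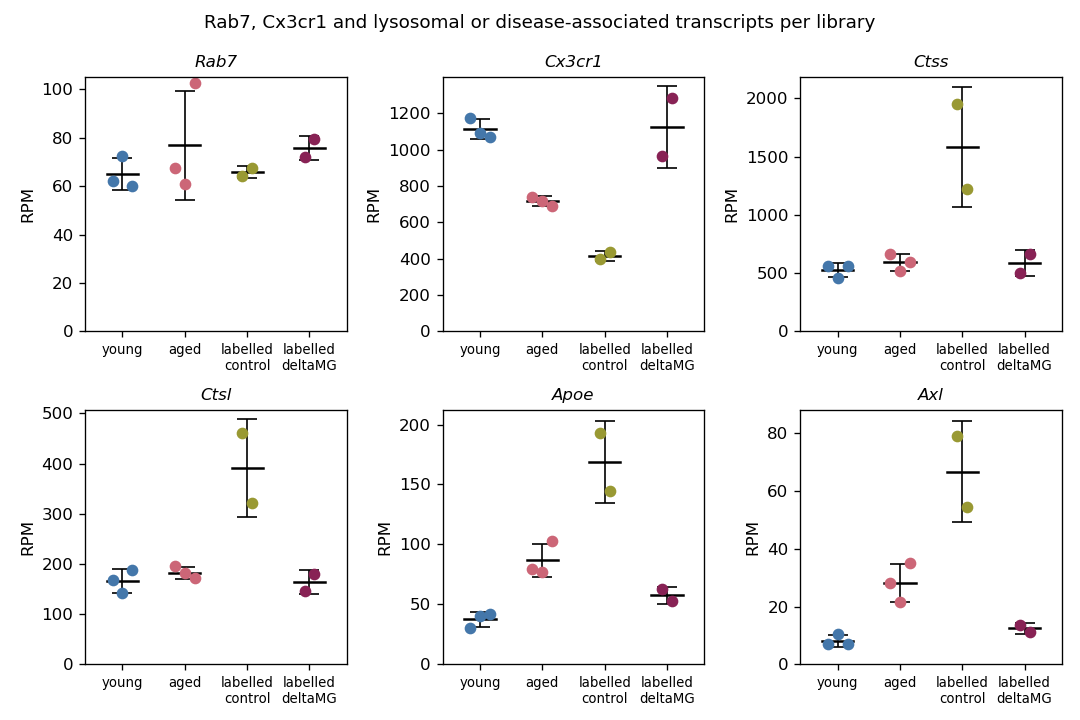
RPM per library for 6 genes in the 4 groups, with each point a library, the horizontal bar the group mean and the whiskers 1 SD. Rab7 lies between 60.0 and 103 RPM in all 10 libraries, while Cx3cr1 is at 398 and 437 RPM in the libraries labelled control and at least 689 RPM elsewhere.

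The first comparison asked how microglial transcripts differ between aged and young mice. In aged libraries the list of homeostatic microglia genes moved down, with 14 of 30 members called. The lists of MHC class I (2 of 5 called) and class II (3 of 6), of interferon response (5 of 12), of cytokines and chemokines (8 of 18) and of disease-associated microglia (12 of 25) moved up. These calls were made with a preset correlation and were lost with an estimated one (adjusted p = 0.138 to 0.208 with an estimated correlation). P2ry12, an ADP receptor that marks resting microglia, fell from 1256 RPM ± 169 (SD, n = 3) in young to 696 RPM ± 152 (SD, n = 3) in aged libraries, a log2 fold change of -0.86 with a standard error of 0.16 and a limma adjusted p of 0.00645. Cd74, the invariant chain of MHC class II, rose from 30.8 RPM ± 7.69 to 105 RPM ± 34.3 (SD, n = 3 each), a 3.27-fold change with a limma adjusted p of 0.000463. Apoe, a lipid carrier, rose 2.28-fold, from 37.5 RPM ± 6.58 to 86.7 RPM ± 14.0 (SD, n = 3 each), with a limma adjusted p of 0.000799. Fold changes are on the log2(RPM + 1) scale, which understates the change of low genes.

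Of 4151 genes tested, limma called 255 at an adjusted p under 0.05, with 131 higher and 124 lower in aged libraries. A fold of at least 2 was reached by 82 of the higher and 12 of the lower genes. At an unadjusted p under 0.05 there were 894 genes. The ranges of the groups did not overlap for 23.9% of the tested genes, where chance gives 10%. The split between higher and lower calls moved with the scaling, to 221 higher and 107 lower with median-of-ratios rescaling, to 217 and 113 with equal totals and to 167 and 109 with quantile normalization. It was 32 higher and 84 lower among genes of at least 50 RPM in at least 3 libraries. The number of calls depended on single libraries, with 96 calls without young replicate 1, 126 without young replicate 3, 151 without aged replicate 1, 121 without aged replicate 3 and 422 without aged replicate 2. It was 160 without young replicate 2, and leaving out libraries of the other experiment gave 157 without control replicate 1 and 160 without control replicate 2.

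Among genes with a mean of at least 50 RPM and no overlap of ranges, the largest rises were in the proliferation marker Mki67, in Cd74, in the neutrophil chemokine receptor Cxcr2, in Ahnak, in the cytokine Il1b, in Mxd1, in Apoe, in the long noncoding RNA Neat1, in H2-D1 and in the chemokine Ccl3. These ranged from 3.75-fold for Mki67 to 1.78-fold for Ccl3. The largest falls were in Xist, Fat3, P2ry12, Golm1, Rnase4, P2ry13, Gpr34, Sparc, Cx3cr1 and Sgk1. Apart from Xist, they ranged from a 2.05-fold fall of Fat3 to a 1.55-fold fall of Sgk1. Of these 20 genes, 15 kept a limma adjusted p under 0.05 when each of the 10 libraries was left out in turn, and 5 lost it at least once. The highest adjusted p was 0.0757 for Cxcr2, 0.137 for Mxd1 and 0.0517 for Cx3cr1, each without young replicate 1. It was 0.0804 for Sparc and 0.119 for Sgk1, each without young replicate 3. With the neutrophil score as covariate the calls of Mxd1, Sparc and Sgk1 were lost (adjusted p = 0.0518, 0.10 and 0.094), at log2 fold changes of 0.59 (1.33 without the score), -0.45 (-0.66) and -0.51 (-0.63).

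The young and aged libraries differed in sex-linked transcripts. Xist, the noncoding RNA of the inactive X chromosome (chromosome X), was at 1715 to 1771 RPM in the young and at 0.127 to 0.940 RPM in the aged libraries. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 35.7 to 48.7 RPM in the aged libraries and to at most 0.288 RPM in the young. The young libraries therefore carried the transcripts of females and the aged those of males, so that age and sex cannot be separated in this comparison. Among the 255 calls, 9 lay on the X or Y chromosome, which held 140 and 1 of the 4151 tested genes. The libraries labelled control and deltaMG carried both, with Xist at 924 to 1562 RPM and Y-linked sums of 9.11 to 25.8 RPM. Each of them therefore held transcripts of both sexes. Y-linked sums were 19.3 and 25.8 RPM in the libraries labelled control and 20.3 and 9.11 RPM in those labelled deltaMG. The mix of sexes thus differed between libraries, and its effect on the comparison of these groups was not tested.

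**Figure D2:**
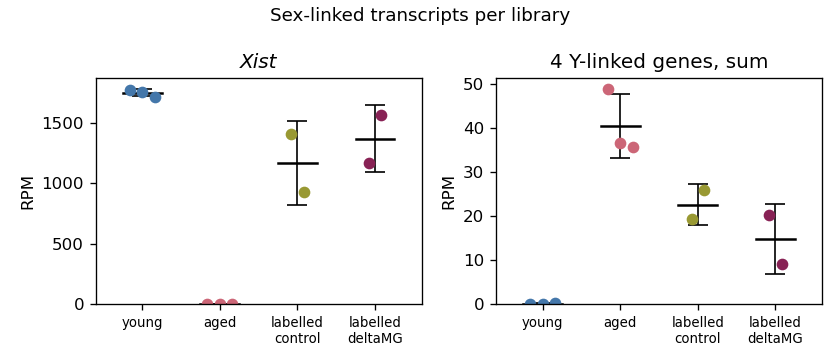
RPM per library for Xist (left) and for the sum of 4 Y-linked genes (right), with each point a library, the bar the group mean and the whiskers 1 SD. Young libraries hold Xist at 1715 to 1771 RPM and Y-linked sums of at most 0.288 RPM, aged libraries hold the reverse, and the libraries labelled control and deltaMG hold both.

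Of 31 homeostatic microglia genes in the table, 30 were tested. In aged libraries 14 fell and none rose, 23 fell when adjusted over the list alone, and the median log2 fold change was -0.47 (camera adjusted p = 1.78e-14; adjusted p = 0.138 with an estimated correlation). Golm1 fell from 191 RPM ± 24.5 to 111 RPM ± 16.5 and P2ry13 from 686 RPM ± 63.0 to 416 RPM ± 27.3 (SD, n = 3 each). Gpr34 fell 1.64-fold. Cx3cr1, the fractalkine receptor, fell 1.55-fold, from 1112 RPM ± 55.3 to 717 RPM ± 26.1 (SD, n = 3 each).

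The disease-associated microglia list had 25 tested members, of which 12 rose and none fell in aged libraries, and 15 rose when adjusted over the list alone. Its median log2 fold change was 0.83 (camera adjusted p = 7.73e-13; adjusted p = 0.138 with an estimated correlation). Spp1, which encodes osteopontin, rose 9.04-fold from 1.91 RPM ± 0.606 to 25.5 RPM ± 6.56, the receptor kinase Axl rose 3.18-fold, Cd52 rose 3.17-fold and Apoe rose 2.28-fold (n = 3 each). Of 6 MHC class II genes tested, 3 rose, 5 when adjusted over the list alone, with a median of 1.36 (camera adjusted p = 5.97e-07; adjusted p = 0.138 with an estimated correlation). These were Cd74, H2-Aa at 3.08-fold and H2-Ab1 at 3.32-fold. The class II list summed to 274, 170 and 318 RPM in aged replicates 1, 2 and 3. Markers of border macrophages (58.9, 35.0 and 90.0 RPM) and monocytes (266, 167 and 770 RPM) had the same order there. Of 5 MHC class I genes, H2-D1 and B2m rose, 3 rose when adjusted over the list alone, and the median was 0.52 (camera adjusted p = 0.000895; adjusted p = 0.208 with an estimated correlation). B2m rose 1.51-fold but had an adjusted p of 0.0873 without aged replicate 1.

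Of 12 interferon response genes tested, 5 rose, 6 when adjusted over the list alone, with a median of 0.31 (camera adjusted p = 1.18e-06; adjusted p = 0.138 with an estimated correlation). Ifi204 rose 3.21-fold, Ifitm3 rose 2.90-fold and Oasl2 rose 2.62-fold, the last with an adjusted p of 0.0514 without young replicate 3. Of 18 cytokine and chemokine genes, 8 rose, 14 when adjusted over the list alone, with a median of 0.71 (camera adjusted p = 2.29e-10; adjusted p = 0.138 with an estimated correlation). Il1b rose 2.69-fold, Tnf 2.09-fold, Ccl3 1.78-fold and the receptor Tlr2 1.77-fold.

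In the cell cycle list 3 of 5 tested genes rose, 4 when adjusted over the list alone, namely Top2a at 4.01-fold, Mki67 at 3.75-fold and Cenpf at 3.28-fold for the calls over all genes (list median 1.71, camera adjusted p = 1.38e-05; adjusted p = 0.192 with an estimated correlation). The list summed to 255, 250 and 644 RPM in aged replicates 1, 2 and 3, and aged replicate 3 also had the highest neutrophil and monocyte sums, 4301 and 770 RPM. Of 23 ribosomal protein genes, Rps15 and Rpl36al rose, 6 rose when adjusted over the list alone, and the median was 0.45 (camera adjusted p = 3.66e-08; adjusted p = 0.208 with an estimated correlation). Of 23 immediate early and stress genes, Nr4a1 rose 1.66-fold, also 1 when adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.000984; adjusted p = 0.321 with an estimated correlation). Without young replicate 1, adjusted p was 0.104 for Rps15, 0.10 for Rpl36al and 0.117 for Nr4a1.

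Lysosomal genes did not move as a list in the ageing comparison, with 1 of 43 tested members lower, also 1 when adjusted over the list alone, and a median of 0.02 (camera adjusted p = 0.995). The member was Arsb, an arylsulfatase, at 1.45-fold lower, with an adjusted p of 0.0889 without young replicate 1. No tested member was called for the vacuolar ATPase (13 tested, median 0.17), for late endosome fusion and retromer (20, 0.02), for autophagy (11, 0.04) or for nuclear oxidative phosphorylation (6, 0.14). These 4 lists had camera adjusted p values of 0.145, 0.995, 0.995 and 0.198. In lipid transport and storage 2 of 13 rose and 1 fell (camera adjusted p = 0.198), with Apoe and Lpl higher and Mylip lower. In phagocytosis and complement 4 of 23 rose and 1 fell (camera adjusted p = 0.133), with Axl, Clec7a and Cd93 among the higher and the phagocytic receptor Mertk lower. In iron and oxidative stress the ferritin genes Fth1 and Ftl1 rose, 2 of 11 (camera adjusted p = 0.198). Apoe, Lpl, Axl, Clec7a and Fth1 are also on the disease-associated list. Without young replicate 1 the adjusted p was 0.157 for Mylip, 0.173 for Mertk and 0.174 for Ftl1, and it was 0.154 for Lpl without aged replicate 1 and 0.0514 for Cd93 without young replicate 3.

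**Figure D3:**
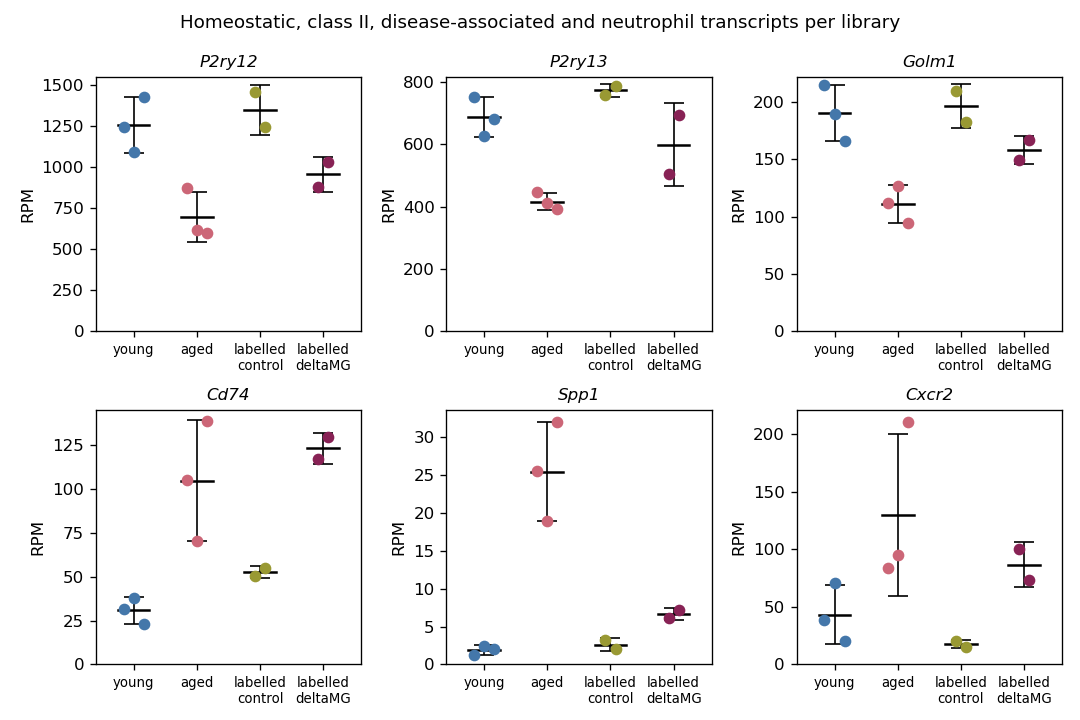
RPM per library for 6 genes in the 4 groups, with each point a library, the bar the group mean and the whiskers 1 SD. P2ry12, P2ry13 and Golm1 were lower and Cd74, Spp1 and Cxcr2 higher in aged than in young libraries, and Cxcr2 reached its highest value in aged replicate 3.

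The neutrophil and monocyte lists passed the test in the ageing comparison, with the highest sums in aged replicate 3. All 11 neutrophil genes had a positive log2 fold change, 1 of them called, Cxcr2, also 1 when adjusted over the list alone (median 1.01, camera adjusted p = 1.38e-05; adjusted p = 0.321 with an estimated correlation). The neutrophil genes summed to 559 to 1425 RPM in young libraries and to 1670, 965 and 4301 RPM in aged replicates 1, 2 and 3, so that aged replicate 2 lay within the range of the young. Without aged replicate 3 the median was 0.41. Of 6 monocyte genes, Ccr2, Itga4 and Fn1 rose, 5 when adjusted over the list alone (median 1.23, camera adjusted p = 1.38e-05; adjusted p = 0.208 with an estimated correlation). Itga4 had an adjusted p of 0.107 without young replicate 3 and Fn1 of 0.109 without young replicate 1. The monocyte median was 0.79 without aged replicate 3. The neutrophil score is the mean log2 value of these same 11 genes. As a covariate it takes out their shared change, so the list's lost call was fixed in advance (median -0.01, camera adjusted p = 0.364). In that fit the monocyte median fell to 0.43, the cytokine median to 0.45, the cell cycle median to 1.04 and the MHC class I median to 0.34. The phagocytosis list passed (median 0.02, camera adjusted p = 0.0352). The log2 fold change there was 0.83 for Il1b (1.43 without the score), 1.04 for Mki67 (1.91), 1.04 for Ahnak (1.60) and 0.57 for H2-D1 (0.88). For Cxcr2, itself part of the score, it was 0.83 (1.60).

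The second comparison asked how the libraries labelled Rab7 deltaMG differ from those labelled Rab7 control. In the libraries labelled deltaMG, the lysosomal list (13 of 43 called) and the disease-associated list (15 of 25) moved down. Both calls were lost with an estimated correlation (adjusted p = 0.309 with an estimated correlation). Cx3cr1, Hspa1a and Hspa1b were higher there than in the libraries labelled control, whose means for these genes were the lowest of all groups. Cathepsin S, Ctss, fell from 1583 RPM ± 515 in the libraries labelled control to 586 RPM ± 114 in those labelled deltaMG (SD, n = 2 each), a log2 fold change of -1.41 with a standard error of 0.21 and a limma adjusted p of 0.00169. Apoe fell 2.87-fold, from 169 RPM ± 34.5 to 57.7 RPM ± 7.12 (SD, n = 2 each), with a limma adjusted p of 0.00077. Cx3cr1 (chromosome 9, 119901616 to 120069879, minus strand, GRCm38) rose 2.67-fold, from 417 RPM ± 27.4 to 1125 RPM ± 226 (SD, n = 2 each), with a limma adjusted p of 0.000158.

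Of the 4151 genes, limma called 157, with 50 higher and 107 lower in the libraries labelled deltaMG. A fold of at least 2 was reached by 33 of the higher and 58 of the lower genes, and 780 genes had an unadjusted p under 0.05. Ranges did not overlap for 51.8% of tested genes, where chance gives 33.3%. Leaving out single libraries gave 25 calls without the library labelled control replicate 1, 71 without control replicate 2, 59 without deltaMG replicate 1, 86 without deltaMG replicate 2 and 317 without aged replicate 3. The excess of lower calls was absent in some of the fits, with 162 higher and 155 lower without aged replicate 3, 258 and 252 with own groups only and 176 and 181 with array weights. When an arm held 1 library, that library was assumed to vary like the other groups.

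By the same rule as above, the largest rises included Cxcr2, Il1b, Mxd1, Cx3cr1, the heat shock genes Hspa1b and Hspa1a, Stk17b, Cd74 and Ahnak, from 4.62-fold for Cxcr2 to 2.25-fold for Hspa1a. The largest falls were in Apoe, Ctss, Serpine2, Ctsl, Npc2, Ctsz, Cd34, Mfsd1, Timp2 and Slc23a2, from 2.87-fold for Apoe to 2.04-fold for Slc23a2. Of the 20 genes selected by the rule, Cx3cr1, Apoe, Ctsz and Timp2 kept a limma adjusted p under 0.05 when each library was left out, and the other 16 lost it at least once. Without the library labelled control replicate 1 the adjusted p was 0.0537 for Ctss, Ctsl and Mfsd1, 0.0605 for Npc2, 0.0726 for Serpine2, 0.143 for Slc23a2, 0.216 for Cd34, 0.205 for Cd74, 0.0597 for Hspa1a and 0.0670 for Hspa1b. Without deltaMG replicate 1 it was 0.159 for Cxcr2, 0.150 for Il1b, 0.327 for Mxd1 and 0.327 for Ahnak, and without control replicate 2 it was 0.151 for Stk17b. With the neutrophil score as covariate the calls of Mxd1 (adjusted p = 0.296), Stk17b (0.104), Cd74 (0.131), Ahnak (0.376) and Slc23a2 (0.0694) were lost, at log2 fold changes of 0.47, 0.56, 0.59, 0.34 and -0.67 (1.62, 1.22, 1.21, 1.21 and -1.03 without the score). Those of Il1b and Cxcr2 were kept at a smaller log2 fold change, 0.79 for Il1b (1.71 without the score) and 1.00 for Cxcr2 (2.21). Cxcr2 is itself part of the score. Cx3cr1 stayed at 1.51 and Hspa1a at 1.48.

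Of 43 lysosomal genes tested, 13 fell and none rose in the libraries labelled deltaMG, and 22 fell when adjusted over the list alone. The median log2 fold change was -0.50 (camera adjusted p = 2.66e-15; adjusted p = 0.309 with an estimated correlation). Ctsz, Ctsl and Ctsb, which encode cathepsins, fell 2.18-fold, 2.36-fold and 1.96-fold. All of these are also on the disease-associated list. Ctsb had an adjusted p of 0.0537 without control replicate 1. Of 25 disease-associated microglia genes, 15 fell and none rose, and adjusted over the list alone 17 fell and 3 rose, with a median of -0.998 (camera adjusted p = 2.01e-11; adjusted p = 0.309 with an estimated correlation). Axl fell 4.97-fold, from 66.6 RPM ± 17.4 to 12.4 RPM ± 1.84, and Cd9 fell 3.65-fold (SD, n = 2 each).

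In lipid transport and storage 4 of 13 fell, namely Apoe, Npc2, Npc1 and Soat1, and 5 fell and 1 rose when adjusted over the list alone (median -0.34, camera adjusted p = 0.00153; adjusted p = 0.309 with an estimated correlation). Of these, Apoe is also on the disease-associated list and Npc1 and Npc2 are also on the lysosomal list. In phagocytosis and complement 5 of 23 fell, and 8 fell and 2 rose when adjusted over the list alone (median -0.28, camera adjusted p = 0.0076; adjusted p = 0.426 with an estimated correlation). Tyrobp fell 2.00-fold, C3ar1 1.57-fold and Trem2 1.60-fold. Axl fell as well, and Axl, Tyrobp and Trem2 are also on the disease-associated list. Of 13 vacuolar ATPase genes Atp6v1c1 fell 1.95-fold, and 4 fell when adjusted over the list alone (median -0.28, camera adjusted p = 0.0137; adjusted p = 0.396 with an estimated correlation). Of 23 ribosomal protein genes Rps6 fell and Rpl29 rose, and adjusted over the list alone 6 fell and 1 rose (median -0.54, camera adjusted p = 7.45e-05; adjusted p = 0.396 with an estimated correlation). The calls of Npc1, C3ar1, Trem2, Tyrobp, Soat1, Rps6, Rpl29 and Atp6v1c1 were each lost when at least 1 library was left out. The highest adjusted p was 0.370 for Npc1, 0.301 for C3ar1, 0.298 for Trem2, 0.216 for Tyrobp, 0.367 for Soat1, 0.304 for Rps6, 0.390 for Rpl29 and 0.182 for Atp6v1c1.

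Among 23 immediate early and stress genes 4 rose, 6 when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 4.26e-06; adjusted p = 0.366 with an estimated correlation). Hspa1a rose 2.25-fold, Hspa1b 2.36-fold, the co-chaperone Dnajb1 1.73-fold and Nr4a1 1.85-fold. The list summed to 2295 and 2135 RPM in the libraries labelled control and to 2959 and 3312 RPM in those labelled deltaMG. In young libraries the sums were 2715 to 3332 RPM and in aged 3072 to 3843 RPM. The libraries labelled control were thus the lowest, and those labelled deltaMG lay within the range of the young. Without control replicate 2 adjusted p was 0.102 for Dnajb1 and 0.229 for Nr4a1. Of 6 MHC class II genes Cd74 rose, and 4 rose when adjusted over the list alone (median 0.97, camera adjusted p = 0.0205; adjusted p = 0.426 with an estimated correlation). All 11 tested neutrophil genes had a positive log2 fold change, with Cxcr2 called and 10 called when adjusted over the list alone (median 1.63, camera adjusted p = 4.97e-07; adjusted p = 0.394 with an estimated correlation). They summed to 694 and 460 RPM in the libraries labelled control and to 1822 and 1186 RPM in those labelled deltaMG. None of 6 monocyte genes was called over all genes and 5 rose when adjusted over the list alone (median 1.42, camera adjusted p = 9.37e-05; adjusted p = 0.394 with an estimated correlation). With the neutrophil score as covariate the stress list kept its call with a median of 0.15 (camera adjusted p = 1.52e-05). Those of class II (median 0.35, camera adjusted p = 0.139) and monocyte genes (0.10, 0.582) were lost. The neutrophil list lost its call too (-0.17, 0.490), which was fixed in advance because the score is made from its genes. The medians of the vacuolar ATPase and of phagocytosis and complement were then lower, -0.55 and -0.48.

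The homeostatic list did not move as a whole (median -0.05, camera adjusted p = 0.489), although 2 of 30 rose, Cx3cr1 among them, and adjusted over the list alone 2 rose and 4 fell. The interferon (median 0.14, camera adjusted p = 0.225), MHC class I (-0.15, 0.140), cytokine (0.00, 0.164), late endosome fusion (-0.05, 0.266), autophagy (-0.05, 0.329), iron (-0.12, 0.335), cell cycle (0.17, 0.548) and oxidative phosphorylation (-0.20, 0.292) lists did not pass the test either. In these lists Il1b, Ifitm3, Ptgs2 and Hmox1 rose, and B2m and the autophagy receptor Sqstm1 fell. Without control replicate 1 the adjusted p was 0.334 for Ifitm3 and 0.199 for B2m. It was 0.406 for Ptgs2 and 0.307 for Sqstm1 without deltaMG replicate 1, and 0.211 for Hmox1 without control replicate 2. With the neutrophil score as covariate the MHC class I (median -0.43, camera adjusted p = 0.0110) and cell cycle lists (-0.61, 0.0349) passed the test.

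**Figure D4:**
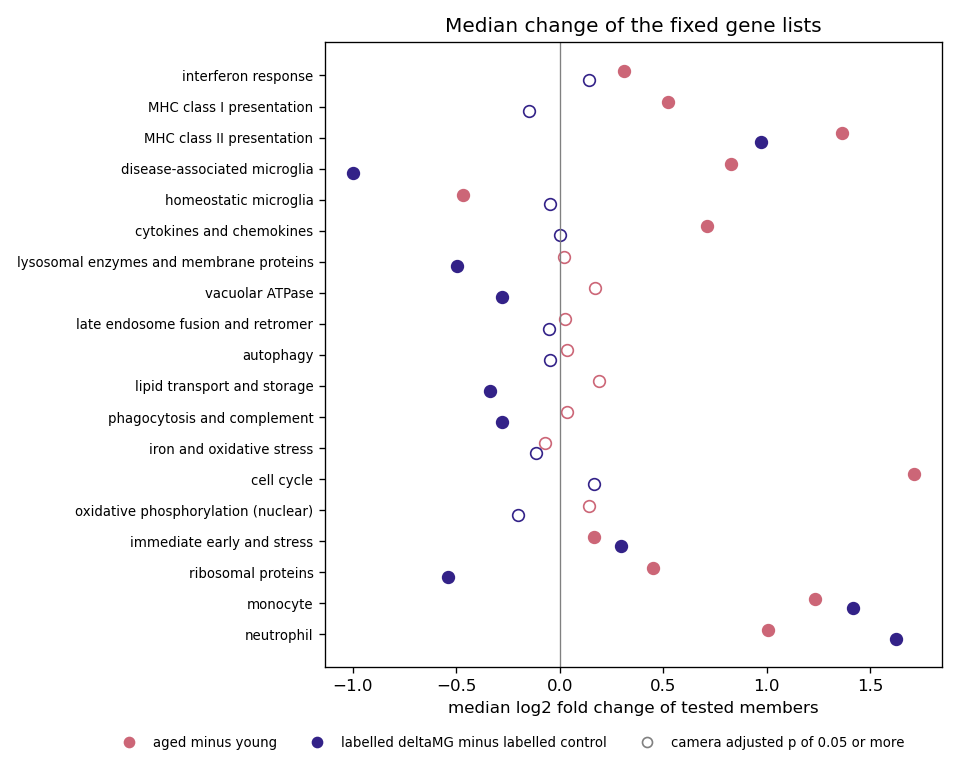
Median log2 fold change of the tested members of 19 gene lists in the ageing comparison and between the libraries labelled deltaMG and control, with filled points for camera adjusted p under 0.05. The disease-associated list has medians of 0.83 and -0.998, and the lysosomal list of 0.02 and -0.50.

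For 13 other lists fewer than 3 members passed the filter. Their summed levels were, in young, aged, labelled control and labelled deltaMG libraries, 22.3, 27.6, 21.2 and 21.3 RPM for oligodendrocyte and myelin genes, 43.4, 38.3, 52.8 and 39.2 RPM for astrocyte genes and 8.40, 19.7, 8.18 and 13 RPM for neuron genes. Endothelial genes were at 21.7, 27.1, 28.1 and 23.7 RPM, border macrophage genes at 31.5, 61.3, 46.0 and 53.1 RPM and choroid plexus and ependymal genes at 115, 135, 3.63 and 66.3 RPM. B cell genes were at 3.74, 7.94, 20.7 and 5.46 RPM, of which Cd22 alone made up 22.3 of 22.6 and 18.2 of 18.8 RPM in the 2 libraries labelled control, and cholesterol synthesis genes at 49.4, 70.5, 62.8 and 56.6 RPM. Oligodendrocyte precursor, mural cell, T and NK cell and erythroid genes did not exceed 8.08 RPM in any group mean. No mitochondrially encoded gene was listed.

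The third comparison set the change between the libraries labelled control and deltaMG beside that of ageing. Below, with age means aged against young libraries, where age and sex cannot be separated. These 2 changes use different libraries but share 1 estimate of the spread for each gene, so their calls are not independent. The counts below for independent lists are therefore a description and not a chance level. Of the 4151 genes, 34 were called in both, as labelled 13 in the same and 21 in opposite directions, and with the labels exchanged 21 in the same and 13 in opposite directions. In the same direction 11 genes rose in both, where independent lists give 1.58, among them Il1b, Cd74, Cxcr2, Ahnak and Mxd1, and 2 fell in both, where independent lists give 3.20, namely Nek6 and Zfp697. Another 14 rose with age and fell in the libraries labelled deltaMG, where independent lists give 3.38, among them Axl, Chst2, Apoe, Ly9, Cd83 and Cst7. A further 7 fell with age and rose in the libraries labelled deltaMG, where independent lists give 1.49, among them Gpr165, Tet1, Cx3cr1 and Serpinf1. The number called in both was 8 without control replicate 1, 12 without control replicate 2, 15 without either library labelled deltaMG, 14 without young replicate 1, 20 without young replicate 3, 19 without aged replicate 1 and 81 without aged replicate 2. The balance of same and opposite directions moved too, to 48 and 33 without aged replicate 2, 22 and 22 with own groups only, 9 and 9 at 2-fold, 0 and 8 without control replicate 1 and 0 and 11 with no filter.

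The difference between both effects was called for 199 genes, 88 higher and 111 lower, and for 251 genes with the labels of the second comparison exchanged, 110 higher and 141 lower. As labelled there were 71 calls without control replicate 1, 114 without control replicate 2, 102 without deltaMG replicate 2 and 132 without young replicate 1. The sulfotransferase gene Chst2 rose 4.23-fold with age and fell 15.8-fold in the libraries labelled deltaMG, from 81.6 RPM ± 4.15 to 4.57 RPM ± 2.74 (SD, n = 2 each). Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a Pearson r of 0.125 and a Spearman rho of 0.022, and with the neutrophil score as covariate r was -0.10. Of 30 relabellings of the libraries within each experiment, 16 gave an absolute r at least as large. The 131 genes higher with age had a median log2 fold change of 0.29 in the libraries labelled deltaMG (camera p = 0.0131; p = 0.603 with an estimated correlation), and the 124 lower genes had a median of 0.07 (camera p = 0.0108; p = 0.514 with an estimated correlation). In each alternative fit these sets were called anew, so they no longer held the same genes. With the neutrophil score as covariate, the 77 genes then called higher with age had a median of -0.14 and no camera call. In the main fit the neutrophil list moved up in both comparisons. The higher set lost its call without young replicate 1, young replicate 3 and deltaMG replicate 1, and the lower set without control replicate 1 and deltaMG replicate 2, where its median was -0.07.

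**Figure D5:**
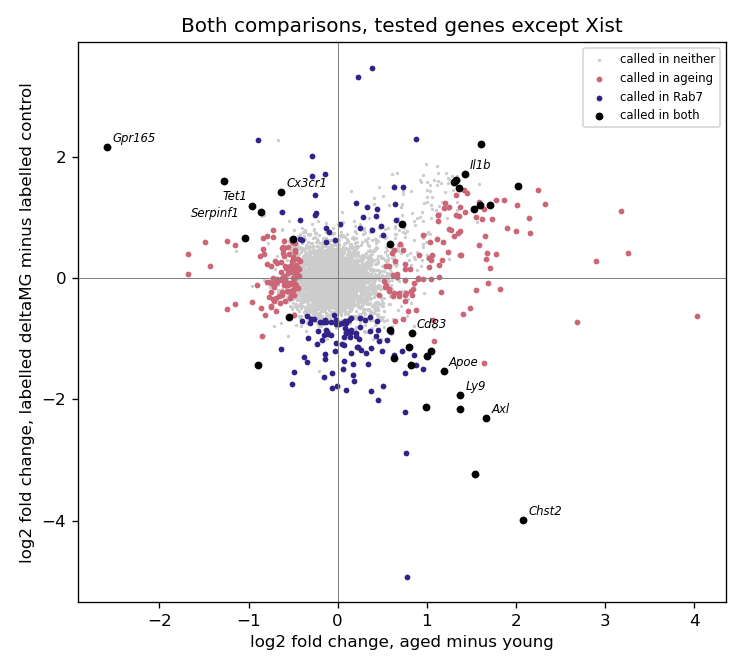
Log2 fold change in ageing (x) against that between the libraries labelled deltaMG and control (y) for the tested genes except Xist, coloured by where a gene was called. Of 34 genes called in both, 21, among them Axl, Apoe, Chst2 and Cx3cr1, lie in the quadrants of opposite direction as labelled, and 13 would with the labels exchanged.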

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

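The tests of exchanged labels, of neutrophil admixture and of sex below were chosen after the results were seen.

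Of 21 genes called in both comparisons in opposite directions, the 9 among the genes named by rule for both follow. They were selected for opposite calls, so that the limma test of the difference, which each passed, adds no support of its own. As log2 differences, the second minus the first, Axl was at -3.98, Chst2 at -6.06, Apoe at -2.71, Ly9 at -3.30, Cd83 at -1.73, Gpr165 at 4.75, Tet1 at 2.14, Cx3cr1 at 2.05 and Serpinf1 at 1.95. With the labels of the second comparison exchanged these differences were 0.65, 1.90, 0.33, 0.54, 0.07, 0.42, -0.23, -0.78 and -0.22, of which those of Chst2 and Cx3cr1 passed the test, so that the pattern rests on the labels.

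The lower lysosomal and disease-associated transcripts and higher Cx3cr1 in the libraries labelled deltaMG were set against 2 technical explanations. For neutrophil admixture, a fit with the neutrophil marker score as covariate left the lysosomal median at -0.47 (-0.50 without it). This argues against neutrophil admixture as the whole cause only if the slope of that fit, taken from the spread within all 4 groups, holds between these 2 groups. Their scores did not overlap, at 5.23 and 4.59 in the libraries labelled control and 6.77 and 6.17 in those labelled deltaMG. If the labels of the 2 groups were exchanged, the libraries labelled control would differ from young wild-type libraries and those labelled deltaMG would resemble them. The former differed in 365 genes and the latter in 5, and Cx3cr1 was 2.66-fold lower than young in the libraries labelled control (limma adjusted p = 3.49e-05) and differed from young by a log2 fold change of 0.0033 in those labelled deltaMG (adjusted p = 0.995). Exchanged labels may therefore be a candidate explanation, but Rab7 itself does not decide. The young libraries belong to another experiment and are female, while the libraries labelled control and deltaMG hold transcripts of both sexes. An effect of the mutation as labelled stays open. The 2 libraries labelled control also stood apart in choroid plexus and ependymal transcripts. These summed to 4.01 and 3.24 RPM there and to 36.2 to 195 RPM elsewhere. The 365 calls against 5 can therefore not be tied to the labels alone.

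Transcripts of 4 Y-linked genes summed to 48.7, 36.6 and 35.7 RPM in the 3 aged libraries, against at most 0.288 RPM in the young. The lower homeostatic and higher disease-associated and class II transcripts in aged libraries were set against neutrophil admixture and sex. With the neutrophil marker score as covariate the homeostatic median was -0.42 (-0.47 without it), the disease-associated median 0.59 (0.83) and the class II median 0.97 (1.36). In that fit 7 homeostatic and 7 disease-associated genes were called (14 and 12). These values argue against neutrophil admixture as the whole cause. The score holds neutrophil markers only, so admixture of monocytes or border macrophages was not tested. Of the 255 ageing calls 9 lay on the X or Y chromosome, which held 140 and 1 of the 4151 tested genes. The median log2 fold change was 0.006 for X genes and -0.05 for autosomal genes. Sex of the mice and age cannot be told apart for these or the other calls. All young libraries carry female and all aged libraries male transcripts. The real split of the 6 libraries gave 255 calls and the highest of the other splits 0 (1 of 10 splits as large), and for the lists that moved 11 and 11 (2 of 10 splits as large). The other split with 11 lists joined young replicates 1 and 3 and aged replicate 2, at neutrophil scores of 5.82, 5.04 and 5.79. The libraries set against them had scores of 6.38, 6.54 and 7.90. A grouping by neutrophil score thus moved as many lists as the real one, with 0 gene calls. Whether these were the same lists was not tested. With 10 splits no share under 0.05 is possible.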

How the results depend on the processing

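Planned count models (quasi-likelihood and size-factor based) were not run, since whole reads were not recovered. Voom on estimated reads, a minimum of 1 RPM, the neutrophil score, leaving out Xist and Y-linked genes and, for difference calls, exchanged labels (251) were added after the data were seen. For named genes, 3784 of 4345 alternative values kept their side of the threshold, some of them uncalled with the other sign, 393 lost and 168 gained a call and 0 reversed a called direction. For changes below, filters alter the number of genes tested (18007 with no filter, 4151 in the main fit) and left-out libraries the number of samples, and the cause was not tested. At low depth, 1 read is worth up to 0.164 RPM.

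Ageing calls (255) were 94 at 2-fold, 445 at adjusted p under 0.1, 131 with no filter, 116 at 50 RPM, 121 with own groups only, 138 with voom and 141 with the neutrophil score. Calls between the libraries labelled deltaMG and control (157) were 91, 287, 88 and 62 under the first 4 of these, 510 with own groups only and 357 with array weights. Difference calls (199) were 115 with no filter, 86 at 50 RPM, 344 with array weights and 467 with the neutrophil score. Genes called in both (34) were 18, 89, 11 and 16 under the first 4, 61 with median-of-ratios, 63 with equal totals, 80 with array weights and 17 with voom. At 50 RPM 7 lists moved in ageing.

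The sets of genes higher and lower with age were called anew in each setting, also when a library was left out. Their medians therefore come from differing genes. The higher set had a median of 0.29 in the main fit. It had no camera call with no filter (0.081), at 50 RPM (0.10) or with median-of-ratios (0.23). The same held for own groups only (0.37), robust moderation (0.16) and voom (0.31). With the neutrophil score its median was -0.14, also without a call. The lower set had no call with median-of-ratios (0.0497).

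With a replicate block there were 66 ageing calls, 69 between the libraries labelled deltaMG and control, 102 difference calls and 10 in both, and the medians of both sets, 0.34 and 0.14, lost their calls. In ageing, numbers did not pair the libraries, with same-number correlations of -0.39 to -0.14. The other comparison, with 2 libraries per group, yields only 1 such value, 0.116, and its negative for unlike numbers. That value cannot decide on pairing there.

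Leaving out each library gave 96 to 422 ageing calls, 25 to 317 between the libraries labelled deltaMG and control, 71 to 264 difference calls and 8 to 81 in both. The medians ranged from 0.23 to 0.60 for the higher set and from -0.0736, without deltaMG replicate 2, to 0.22 for the lower set. The camera call of the higher set was lost without young replicates 1 and 3 and deltaMG replicate 1, and that of the lower set without control replicate 1 and deltaMG replicate 2. The Rab7 change ranged from 0.13 to 0.27 (-0.21 with the neutrophil score), r from 0.022 to 0.206 (-0.10 with that score), and lists moved from 10 to 11 in ageing and 9 to 11 in the other.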

Other observations

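The tests below were chosen after the results were seen. Choroid plexus transcripts were nearly absent from the libraries labelled control. Ttr, the transthyretin gene, was at 2.23 and 2.26 RPM there, at 20.9 and 57.4 RPM in those labelled deltaMG and at 25.1 to 112 RPM in young and aged libraries. Enpp2 was at 1.63 and 0.705 RPM in the libraries labelled control and at 12.2 to 65.4 RPM in the others. Cd22, a member of the B cell list, showed the opposite, at 22.3 and 18.2 RPM in the libraries labelled control and at 1.26 to 7.21 RPM elsewhere. The whole B cell list summed to 22.6 and 18.8 RPM in the libraries labelled control, so its other members were nearly absent there. Like Axl and Apoe, Cd22 was among the 14 genes called higher in aged libraries and lower in those labelled deltaMG.

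Compared with young libraries, those labelled control had higher lysosomal (median log2 fold change 0.56) and disease-associated transcripts (1.17), while those labelled deltaMG had medians of 0.15 and 0.25. The homeostatic medians were 0.05 and -0.03. These contrasts cross 2 experiments and set libraries with transcripts of both sexes against female ones.

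The higher neutrophil and monocyte lists in the ageing comparison were set against unequal admixture of blood cells. Of 19 markers with a mean of at least 1 RPM, 18 (94.7%) peaked in aged replicate 3, and S100a8 was at 773 RPM and S100a9 at 1446 RPM there. Without it the neutrophil median fell from 1.01 to 0.41 and the monocyte median from 1.23 to 0.79. The markers move together and a rise of these cells in the tissue behind that library would give the same share, so admixture and such a rise cannot be told apart.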
